A study of Drosophila melanogaster with 4 samples.

How the data were processed

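Chromatin from Oregon-R embryos labelled 14 to 16 h was immunoprecipitated with an antibody against HP1c, per the labels, with 2 ChIP samples and 2 input samples. The submitters' processing notes name Bowtie 0.12.7, a read aligner, with no further detail. The region caller, its threshold and the way in which the replicates were combined are not given in the sources used here. The deposited lists hold regions named as significantly enriched, with the start, the end and a score for each region, on FlyBase release 5, per the file headers. There is 1 list per ChIP replicate and 1 list for the replicate set. The score is the authors' own, and no label or header states its scale, so it was used to describe, rank and filter regions within a list. Where scores of matched regions were related between lists, a rank correlation was used. No lists of the input samples were used here: the inputs enter only through the authors' calls, and the labels name each as the input of the ChIP with the same replicate number.

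Groups and replicate numbers were taken from the sample titles. Widths, covered bases and scores were summarised per list. A region counted as overlapped when it shared at least 1 base with a region of the other list. Chance overlap came from 1000 circular shifts of one list within each chromosome sequence, which keeps the number, width and spacing of regions, with a one-sided p. Pairs of matched regions were those that shared the most bases with each other in both directions. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Regions per Mb used the sequence lengths in the file headers; ratios to the arms 2L, 2R, 3L and 3R have exact binomial intervals and two-sided tests, adjusted by Benjamini-Hochberg. No regions lay on the sequence Uextra, which was left out. Windows of 1 Mb on X and on the autosomal arms were compared by a two-sided permutation test of the mean with 100000 resamples, and the scores of regions on X, 4 and heterochromatin were set against those on the autosomal arms in the same way. The part of each arm nearest the centromere and that nearest the telomere were each 20% of its length, as ordered on the reference maps of the arms. Gaps between regions were compared with 1000 random placements that kept widths and chromosomes.

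Apart from the widest regions and those ranked 1 and 2 by score in the combined list, the regions named in the text follow a rule set before the data were examined: the 20 regions of the combined list with the highest score among those overlapped by both replicates, and the region with the highest score on each chromosome sequence with none among these 20. The wording of the rule left open whether the latter had to be overlapped by both replicates; it was read as not required when the rule was applied, and the 5 regions so named all have no replicate. Most comparisons, tests and alternative settings were also fixed before the data were examined. The tests over windows of 1 Mb were chosen after the results were seen. For the distribution over chromosomes, the plan set the regions of each sequence against its length. It named ratios to the autosomal arms for chromosome 4 and heterochromatin only. The ratios of X and U to the autosomal arms and the tests of scores between chromosomes were not in the plan. The planned distribution over gene features, the genes with a region at the transcription start site and the gene lists fixed beforehand were not run, because the gene table at hand is on release 6, another build than release 5 of the lists, and coordinates were not converted. For the same reason regions are named by position and not by gene.

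The overlap test was tested on simulated data made from the 4669 regions of replicate 1. Lists that copied 0%, 9.21% and 79.4% of these regions gave overlaps of 18.9%, 25.0% and 80.4%, where the copied share and chance overlap together give 18.7%, 24.4% and 80.2%. Of 20 random lists, 2 had p under 0.05. Alternatives were an overlap of at least 50% of both regions, the midpoint inside the other region, the 50% of regions with the highest scores, equal numbers of regions, merging of regions closer than 500 bp, arms only, each replicate list in place of the combined list, and covered bases in place of the number of regions or the reverse. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.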

Results

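HP1c is one of the heterochromatin protein 1 paralogs of Drosophila melanogaster, chromodomain proteins of which HP1a is the best known for its place in pericentric heterochromatin. Its binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type Oregon-R embryos labelled 14 to 16 h, cross-linked with 1.8% formaldehyde. The series holds 4 samples: 2 HP1c ChIP samples and 2 input samples, each input being labelled as the control of the ChIP with the same replicate number. The values below are the regions of significant enrichment called by the authors, 1 list for each ChIP replicate and 1 list for the replicate set, called the combined list here. Positions are given on FlyBase release 5. The lists hold no read counts, so the sequencing depth behind each region is unknown. Nothing in the labels says that the 2 replicates came from separate collections, so the spread between them may be technical, and no test across samples was run: over 2 samples an exact sign test cannot give a two-sided p below 0.5.

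HP1c was enriched at many short stretches of the genome in each replicate. Replicate 1 had 4669 regions covering 11264422 bp, and replicate 2 had 4801 regions covering 12005085 bp. On the arms 2L, 2R, 3L, 3R, X and 4 they covered 9.19% and 9.75% of the sequence. Most regions were a few kilobases wide, with median widths of 2191 bp and 2196 bp. The authors' score of a region, whose scale the labels do not state, had a median of 0.65 in replicate 1 (range 0.18 to 2.99) and 0.79 in replicate 2 (range 0.21 to 3.05). Wider regions had higher scores, with a Spearman rho across regions, which are not independent, of 0.776 and 0.766.

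The replicates answer whether the same places were enriched in both samples, and most were. Of the replicate 1 regions, 3822 (81.9%, exact binomial 95% interval 80.7 to 83.0) were overlapped by a replicate 2 region, and of the replicate 2 regions 3767 (78.5%, 77.3 to 79.6) were overlapped by a replicate 1 region. The shared sequence was 63.5% of all bases that either list covered. On chromosome 4, 45 of 47 replicate 1 regions recurred, on X 844 of 1044, and on the heterochromatin sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) 49 of 67. Of the replicate 2 regions, 38 of 54 on chromosome 4 (70.4%), 823 of 1063 on X (77.4%), 46 of 73 on heterochromatin (63.0%) and 79.5% on the autosomal arms 2L, 2R, 3L and 3R were overlapped. When one list was shifted within each chromosome, a mean of 18.1% of replicate 1 and 17.5% of replicate 2 regions were overlapped, and none of 1000 shifts reached the observed share (highest 20.9% and 20.3%; one-sided permutation test by circular shifts, p = 0.001 for both, the smallest that 1000 shifts can give). The intervals cover counting error only, and neighbouring regions are not independent.

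Regions found in one replicate alone had low scores. The median score of shared regions was 0.76 in replicate 1 and 0.95 in replicate 2, against 0.47 for the 847 and 0.54 for the 1034 regions without a counterpart. Among the 25% of regions with the highest scores, 99.5% of replicate 1 and 98.9% of replicate 2 were shared, and among the 25% with the lowest scores 55.7% and 50.4%. For 3712 pairs of regions that were each other's best match, the scores rose together (Spearman rho 0.812 across pairs) and the midpoints lay a median of 97 bp apart.

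**Figure D1:**
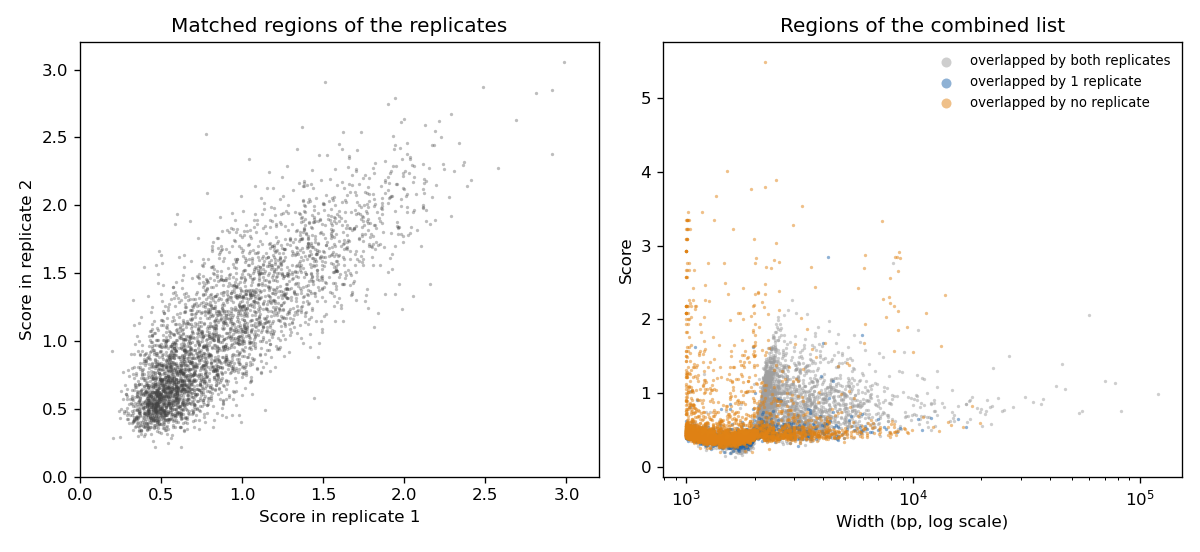
Left, each point is 1 of 3712 pairs of matched HP1c regions, with the authors' score in replicate 1 on the x axis and in replicate 2 on the y axis. Right, each point is 1 of the 8021 regions of the combined list, with its width in bp on a log axis and its score, coloured by the number of replicates that overlap it; regions overlapped by both replicates reach a score of 2.76, and regions overlapped by none reach 5.49.

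Of the 20 regions with the highest combined score that were overlapped by both replicates, 8 were on 2R, 5 on X, 2 on 3R, 2 on 3LHet and 1 each on 2L, 3L and U. The region 2R 18823313 to 18826225 (combined score 2.26) matched the top-ranked region of both replicates, with scores of 2.99 in replicate 1 and 3.05 in replicate 2. The region X 1772672 to 1775485 (combined score 2.12) ranked 4 in replicate 1 and 5 in replicate 2, the region 2R 11014229 to 11017623 (2.07) ranked 2 and 4, the region 2L 18687882 to 18690570 (2.06) ranked 7 and 3, and the region 2R 6045197 to 6049460 (1.98) ranked 5 and 10. Each rank is that of the replicate region with the longest overlap. By these ranks, 12 of the 20 were among the top 100 of replicate 1 and 16 among the top 100 of replicate 2. The region 2R 7855333 to 7859148 ranked 556 in replicate 1 and 14 in replicate 2, and X 1848514 to 1859066 ranked 481 and 1644. The broad region 3L 602995 to 662757 was overlapped by 7 regions of replicate 1 and 9 of replicate 2. Its ranks, 1647 and 174, belong to different places, 639154 to 645409 in replicate 1 and 626123 to 631735 in replicate 2. They do not compare the replicates at 1 locus. Within 3LHet, the region 264884 to 267368 ranked 2 in replicate 2 but 371 in replicate 1, and 541363 to 543892 ranked 18 and 1845. The highest combined score among the 20, 2.76 at X 4989943 to 4998132, had no strong counterpart: the replicate regions overlapped only its edge and ranked 2188 and 2220. With an overlap of at least 50% of both regions required, this region, X 1848514 to 1859066 and 3L 602995 to 662757 lost both replicates, and the others of the 20 kept both. On 2LHet, 2RHet, 3RHet, 4 and XHet, which had none of the 20, the region with the highest combined score was overlapped by no replicate, the 1 on chromosome 4 being 340584 to 348852 (score 2.18).

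HP1c regions were denser on X than on the autosomal arms (2L, 2R, 3L and 3R) in both replicates. X had 46.6 regions per Mb in replicate 1 against 36.1 on the autosomal arms, a ratio of 1.29 (95% interval 1.20 to 1.38), and 47.4 against 37.1 in replicate 2, a ratio of 1.28 (1.19 to 1.37). The regions on X also had higher scores, with a median of 0.70 against 0.64 in replicate 1, 0.83 against 0.77 in replicate 2 and 0.55 against 0.45 in the combined list. The density of the combined list went the other way, with 45.9 regions per Mb on X against 61.6 on the autosomal arms, a ratio of 0.75 (0.70 to 0.80). In the 50% of combined regions with the highest scores, the ratio was 1.12 (1.03 to 1.22). Of the combined regions, 73.1% on X and 45.8% on the autosomal arms were overlapped by both replicates. Such regions had a median combined score of 0.62, against 0.44 for regions without a replicate. The higher combined scores on X are therefore not separate from this difference in make-up.

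Each of these X densities differed from the autosomal arms by an exact binomial test over regions (two-sided, Benjamini-Hochberg adjusted over 12 tests, p = 3.95e-12, 9.27e-12 and 4.61e-19 for replicate 1, replicate 2 and the combined list). Since regions cluster, the 22 windows of 1 Mb on X were also set against the 95 on the autosomal arms. The mean number per window was 47.3 (SD 11.8) against 36.4 (SD 10.0) in replicate 1, 48.1 (SD 12.1) against 37.3 (SD 10.9) in replicate 2 and 46.5 (SD 17.0) against 61.5 (SD 25.1) in the combined list (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give, 5e-05 and 0.00895; adjusted p = 5e-05, 0.000125 and 0.00895 over 5 tests). The mean score on X was 0.868 against 0.784 in replicate 1, 0.995 against 0.926 in replicate 2 and 0.717 against 0.585 in the combined list. These differences of means had adjusted p = 4.5e-05, 0.00012 and 4.5e-05 by a permutation test over regions, 9 tests in all. That test treats clustered regions as independent, so its p-values may be too small. Heterochromatin passed in the combined list (mean score 0.65 against 0.59, permutation test, adjusted p = 0.000292) but in neither replicate (adjusted p = 0.853 and 0.2). Most of its combined regions, 88.5%, were overlapped by no replicate, against 41.1% on the autosomal arms.

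**Figure D2:**
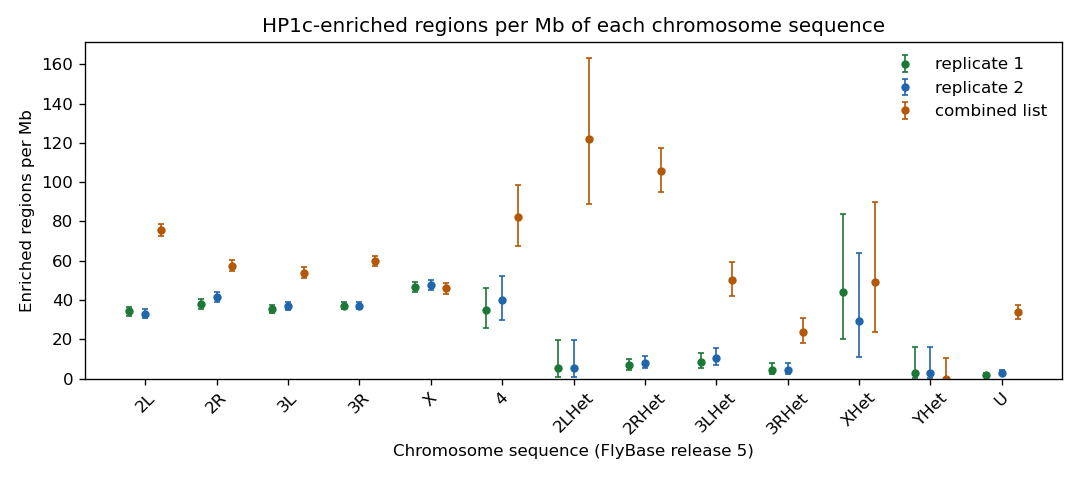
Enriched HP1c regions per Mb on the y axis for each chromosome sequence of FlyBase release 5 on the x axis, for replicate 1, replicate 2 and the combined list. Bars are exact binomial 95% intervals of the count; X lies above the autosomal arms in the replicates (46.6 and 47.4) and below them in the combined list (45.9), and 2RHet has 6.69, 7.91 and 106 regions per Mb.

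The assembled heterochromatin was poor in HP1c regions in both replicates. It had 7.22 regions per Mb in replicate 1 and 7.86 in replicate 2, ratios to the autosomal arms of 0.20 (0.15 to 0.25) and 0.21 (0.17 to 0.27). The unplaced sequence U had 1.89 and 2.89 regions per Mb. In the combined list, heterochromatin had 63.7 regions per Mb, a ratio of 1.03 (0.95 to 1.13), over sequences that went opposite ways: 122 regions per Mb on 2LHet and 106 on 2RHet, 50.1 on 3LHet, 49.0 on XHet, 23.8 on 3RHet and no region on YHet. 2RHet alone went from 22 and 26 regions in the replicates to 348 of the 591 combined ones, and without it the ratio was 0.66 (0.58 to 0.75; exact binomial p = 1.15e-11, not adjusted). Among the heterochromatin sequences, XHet stood apart in the replicates, with 44.1 and 29.4 regions per Mb from 9 and 6 regions. The density of heterochromatin and of U differed from the autosomal arms in both replicates (exact binomial test, adjusted p = 1.15e-66 and 1.2e-65 for heterochromatin), and that of heterochromatin did not pass the test in the combined list (adjusted p = 0.518). The heterochromatin ratio was 1.33 (1.19 to 1.49; exact binomial p = 1.39e-06, not adjusted) in the 50% of combined regions with the highest scores and 0.17 (0.12 to 0.23) among combined regions overlapped by both replicates, which were selected by lists already sparse there. Of the 591 combined heterochromatin regions, 523 (88.5%) were overlapped by no replicate, against 41.1% on the autosomal arms. The combined ratio of U was 0.55 (0.49 to 0.61; exact binomial adjusted p = 3.79e-31). How many reads could be placed in these repeat-rich sequences was not analysed here.

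Chromosome 4, the small autosome whose genes lie within heterochromatin-like chromatin, had a number of HP1c regions per Mb that did not differ detectably from that of the autosomal arms in the replicates. The ratio was 0.96 (0.71 to 1.28) in replicate 1 and 1.08 (0.81 to 1.41) in replicate 2, with 47 and 54 regions, and neither passed the exact binomial test (adjusted p = 0.885 and 0.621). They covered 9.06% of chromosome 4 against 8.62% of the autosomal arms in replicate 1, a ratio of 1.05, and 14.3% against 9.06% in replicate 2, a ratio of 1.57, which was not tested. In replicate 2 their median width was 3218.5 bp, against 2238 bp in replicate 1. Their mean score was 1.06 (SD 0.46) against 0.93 (SD 0.48) on the autosomal arms in replicate 2 and 0.74 (SD 0.31) against 0.78 (SD 0.41) in replicate 1, and neither difference passed the permutation test (adjusted p = 0.0684 and 0.555). The medians were 1.096 against 0.77 and 0.69 against 0.64, so that in replicate 1 the median and the mean differed in direction. In the combined list the chromosome had 111 regions, a ratio of regions per Mb of 1.33 (1.095 to 1.61; exact binomial adjusted p = 0.00548). They covered 33.7% of it against 14.9% of the autosomal arms, a ratio of 2.26, which was not tested. The ratio of regions per Mb fell to 1.16 (0.93 to 1.44) when regions closer than 500 bp were merged.

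The combined list was larger than either replicate list, with 8021 regions covering 19.5 Mb and a median width of 1962 bp. Both replicates overlapped 3571 of them (44.5%, 43.4 to 45.6), 1 replicate overlapped 954 (11.9%), and no replicate overlapped 3496 (43.6%, 42.5 to 44.7). The regions without a replicate were narrow, with a median of 1473 bp, and together covered 6.43 Mb. On X they made up 14.0% of the regions, on 2R 31.4%, on 3L 34.6%, on 3R 39.2%, on 2L 54.6%, on chromosome 4 59.5%, on U 93.5% and on 2RHet 93.1%. In the other direction, the combined list overlapped 82.7% of replicate 1 regions, 90.4% of replicate 2 regions and 95.2% of the replicate 1 regions that replicate 2 shared. Circular shifts gave a mean overlap of 25.5% for replicate 1 and 25.8% for replicate 2, with highest values of 35.8% and 37.1%. The score of a replicate region rose with that of its combined region, with a Spearman rho across regions of 0.711 in replicate 1 and 0.871 in replicate 2.

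Along the arms, the replicates followed each other closely. Over 117 windows of 1 Mb on 2L, 2R, 3L, 3R and X, the number of regions per window had a Spearman rho of 0.887 between replicates, across windows, which are not independent. Combined regions without a replicate gathered in a few windows: 131 lay at 2L 22 to 23 Mb, 98 at 3R 11 to 12 Mb, 88 at 2L 8 to 9 Mb and 77 at 3L 23 to 24 Mb, where the replicates had between 11 and 47 regions. The 12 windows richest in them held 36.4% of the 2513 that lay in these windows, and in 25 windows, 0 of them on X, they outnumbered the regions overlapped by both replicates. They were fewer per window on X than on the autosomal arms (mean 6.36, SD 5.94, against 24.98, SD 23.7; permutation test, adjusted p = 0.00128). Regions overlapped by both replicates, which were selected by lists already denser on X, had a mean of 34.0 (SD 10.9) against 28.5 (SD 8.13). The lower number of regions without a replicate on X is not independent of that density either.

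**Figure D3:**
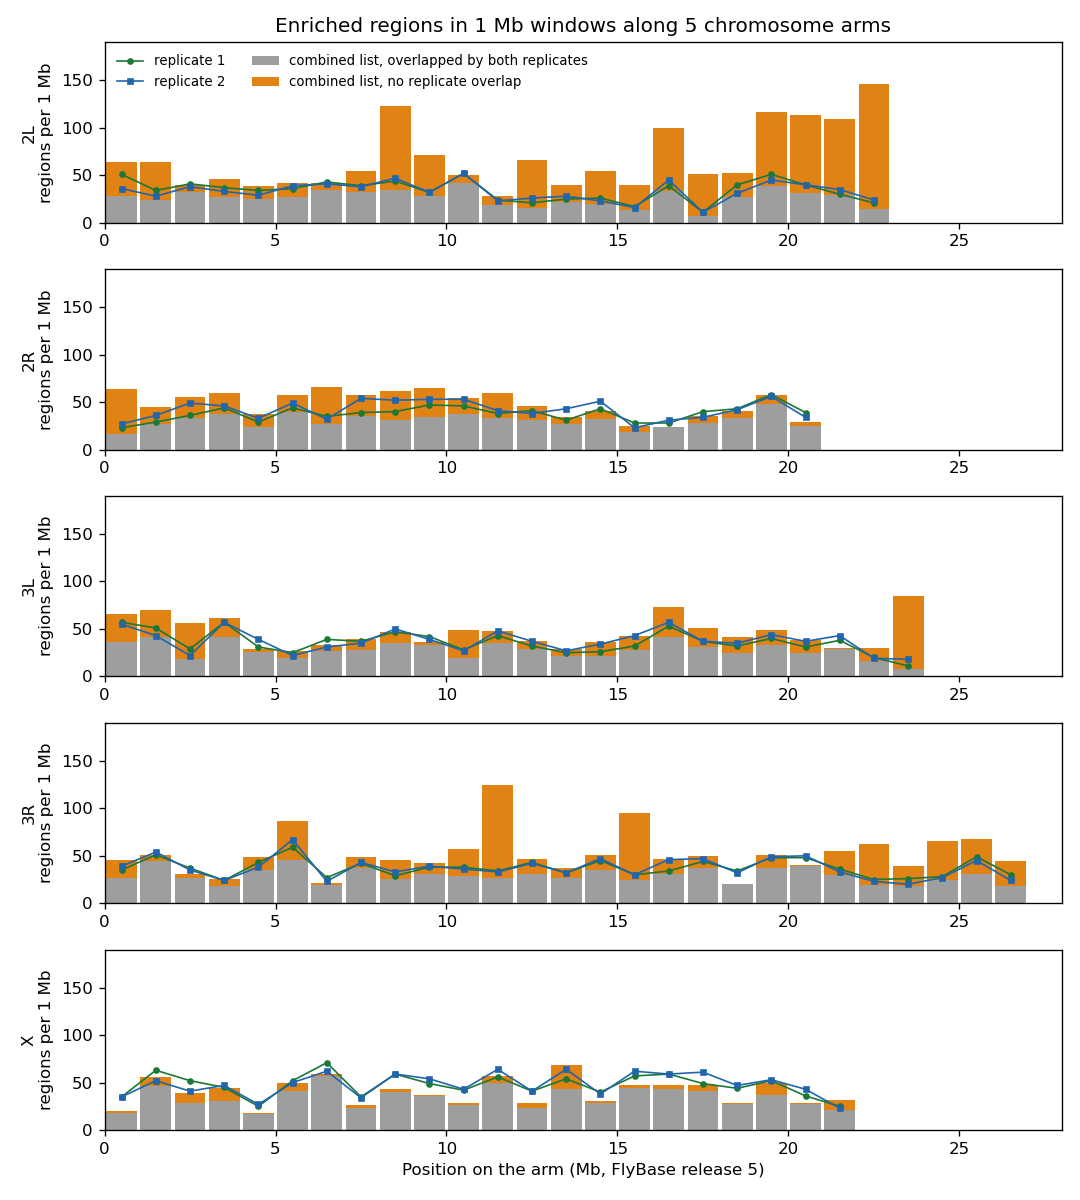
Number of HP1c regions in each 1 Mb window (y axis) along 2L, 2R, 3L, 3R and X (x axis, Mb on FlyBase release 5). Lines are replicates 1 and 2, grey bars are combined regions overlapped by both replicates, and orange bars stacked on them are combined regions overlapped by none, which reach 131 at 2L 22 to 23 Mb; combined regions overlapped by 1 replicate are not drawn.

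HP1c coverage was not higher near the centromeres in the replicates, taken over all arms. The 20% of each arm nearest the centromere was covered to 8.33% in replicate 1 and 9.41% in replicate 2, against 9.28% and 10.1% in the middle of the arms, and the 20% nearest the telomere to 9.78% and 9.09%. The centromere-near part was poorer than the middle on X, with 8.97% against 12.8% in replicate 1 and 9.71% against 14.1% in replicate 2, and on 3L, with 5.65% against 8.17% and 6.97% against 8.99%. It was richer on 2L, with 9.12% against 7.42% and 9.71% against 8.02%, on chromosome 4, with 12.1% against 8.81% and 15.7% against 13.9%, and slightly on 3R, with ratios of 1.04 and 1.06. On 2R the ratio was 0.90 in replicate 1 and 1.06 in replicate 2. In the combined list the centromere-near parts had 16.7% against 13.8%, a ratio of 1.22 that rested on 2L (34.5% against 14.4%): without 2L the ratio was 0.92. The small chromosome 4 was also richer there in the combined list, with 58.0% against 27.8%. Combined regions without a replicate, taken alone, covered 6.26% of the centromere-near parts against 3.26% of the middle. Their coverage was higher near the centromere on 5 of 6 arms, all but 3R. These shares are described without a test, and 3 of 6 arms were higher near the centromere in replicate 1, 4 in replicate 2 and 3 in the combined list.

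HP1c regions lay closer to one another than random placement on the same sequences gave. The median gap to the next region was 9893.5 bp in replicate 1, 9188.5 bp in replicate 2 and 5304 bp in the combined list, against 16655 bp, 16184 bp and 9790 bp for random placement (permutation test over 1000 placements, one-sided p = 0.001 in each list, the smallest they can give). The combined list also held broad regions, with 96 wider than 10000 bp against 2 in replicate 1 and 8 in replicate 2. The widest, 3R 25518698 to 25639490, spanned 120793 bp and was overlapped by 9 regions of replicate 1 and 10 of replicate 2, which covered 19.5% and 21.8% of it. The region 3L 3375762 to 3458545 spanned 82784 bp with 10 and 12 replicate regions, 2L 446110 to 523537 spanned 77428 bp with 5 and 4, and 3R 11808552 to 11878509 spanned 69958 bp with 2 and 2, which covered 6.91% and 6.34% of it. These are the 4 widest regions, a choice made after their values were seen.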

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

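Tests with local shifts, a width minimum, combined regions overlapped by both replicates alone, 1 Mb windows, the combined list on arms only, arms without 2L and heterochromatin without 2RHet were chosen after the results were seen. Of 62 values under alternative settings, 29 kept their direction and their side of the threshold, among them every overlap between replicates (74.1% to 84.5%) and every gap. The density ratio of X in the combined list, 0.75, reversed to 1.28 and 1.29 in the lists of single replicates, to 1.12 in the 50% with the highest scores and to 1.19 among regions overlapped by both replicates, which were chosen by lists already denser on X; it stayed below 1 at 0.76 after merging and over windows, 0.77 in covered bases and 0.83 with the width minimum of the replicates. That of chromosome 4, 1.33, was 0.96 and 1.08 in single replicates, 1.16 after merging and 0.94 among regions overlapped by both replicates, and 2.26 in covered bases, and it kept its call at 1.41 in the 50% with the highest scores and 1.35 with the width minimum. That of heterochromatin, 1.03, was 0.20 and 0.21 in single replicates, 0.17 among regions overlapped by both, 0.66 without 2RHet, 1.33 in the 50% with the highest scores, 0.98 after merging, 0.90 with the width minimum of the replicates and 0.95 in covered bases. The coverage near the centromere over the middle of the arms, 1.22, was 0.90 and 0.93 in single replicates, 1.17 in numbers of regions, 0.99 among regions overlapped by both and 0.92 without 2L. That near the telomere, 1.05, was 1.055 in replicate 1, 0.90 in replicate 2 and 1.0 in numbers of regions. The share of combined regions overlapped by both replicates and by none, 44.5% and 43.6%, moved to 38.4% and 48.3% with 50% of both regions required, 46.7% and 41.9% between the 50% highest-scored regions of each list, 54.4% and 33.4% with the width minimum and 49.6% and 37.4% on arms only. The score difference between shared and unshared regions of replicate 1, 0.29, was 0.30 with 50% of both regions required. Apart from changes that follow from which regions are counted, the cause was not tested. No paired analysis was possible because the inputs that share replicate numbers with the ChIP samples enter here only through the authors' calls, and no model was fitted. Alternatives on gene features, start sites and gene lists were not run. The read depth of the lists is unknown, so weak regions missing from a list are not shown to be absent.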

Other observations

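Of the tests in this part, that of weak regions in the replicate lists was written before its result was seen, and the others were chosen after the results they bear on were seen.

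The 25 highest-scored regions of the combined list, 48 of the highest 50 and 97 of the highest 100 were overlapped by no replicate region. The highest of all was X 13897473 to 13899704, with a score of 5.49 and a width of 2232 bp, followed by 2R 2239518 to 2241033 with 4.01. A candidate explanation is log2 ratios of few reads, which with the smallest control count would put scores at a constant offset plus the log2 of a whole number, to within 1e-06, and with larger counts at fractions. Scores tied in 7 and 6 regions set this ladder. Of the rest of the 50 highest-scored regions without a replicate, 23 of 37 lay on it but only 8 of their 22 distinct scores. Of the 50 highest-scored regions overlapped by both replicates, 0 did. These 2 sets lay at different scores, 2.76 to 5.49 and 1.63 to 2.76, which limits the contrast. Over all regions it was 73 of 3496 (2.09%), the 13 that set the ladder included, and 8 of 3571 (0.22%). The highest score lay 53 units up, and 3 of the 10 highest regions were off the whole-number ladder, at 17.5, 16.3 and 13.6 units, which such fractions allow, so few reads stay open as an explanation; the reads were not analysed here and no biological explanation was tested.

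Combined regions without a replicate made up 43.6% of the list and lay in blocks, with 5 of the 8 richest 1 Mb windows on 2L. A lower width minimum in the combined list was not enough, since 33.4% of combined regions at least 1301 bp wide, the narrowest width in the replicate lists, had no replicate either. Regions without a replicate were not confined to low scores, since 32.1% of the 50% with the highest scores had none against the whole replicate lists. That part begins at a score of 0.47, below the lower quartile of replicate 1 (0.49) and of replicate 2 (0.56). The scale of the score may also differ between lists, so a lower score threshold stays open. Even scatter of chance calls was argued against by a variance over mean of 24.0 per window, above the highest of 1000 random placements, 7.13. A threshold on another statistic or on pooled depth, and differences in copy number between ChIP and input chromatin, could still account for the blocks and were not tested, and no biological explanation was tested.

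The X chromosome was denser than the autosomal arms in both replicates and sparser in the combined list. The higher density in the replicate lists was not confined to weak regions near the threshold. In the 50% with the highest scores the ratio was 1.48 (1.34 to 1.63) in replicate 1 and 1.41 (1.28 to 1.55) in replicate 2. This follows from the higher scores of X regions in both lists, given above, and is not separate support for the density. In the combined list the autosomal arms had 61.6 regions per Mb, against 36.1 and 37.1 in the replicates. On X the net density changed little (46.6, 47.4 and 45.9). Combined regions without a replicate were 2444 of 5949 on the autosomal arms and 144 of 1029 on X. Those overlapped by both replicates or by 1 were 2727 and 778 on the autosomal arms, and 752 and 133 on X. Together, the overlapped ones on X were fewer than the 1044 and 1063 replicate regions, though 1 combined region can overlap several of these. On the autosomal arms they lay between the 3492 and 3582 of the replicates. The lower ratio thus cannot be credited to the autosomal arms alone. Whether weak regions account for it stays open. The ratio of 1.12 (1.03 to 1.22) in the 50% of combined regions with the highest scores prompted this explanation and so cannot test it. A difference of X copy number or of mapping between ChIP and input could not be examined from region lists. Whether the higher density on X follows the biology of HP1c was not tested.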
